A study of Mus musculus with 2 samples.

How the data were processed

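MicroRNAs were measured by sequencing short RNAs, with a size range below 30 stated in the labels, from the hippocampus of female B6CASTF1/J mice aged 25 days. B6CASTF1/J is the first-generation cross of a C57BL/6J and a CAST/EiJ mouse. The labels give 2 biological replicates, each a separate tissue sample and 1 library, and put both in 1 group. The labels call the tissue a layer of the hippocampus and do not say which layer.

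The deposited files hold whole-number read counts per miRNA gene, 1 table per library, with no header line. Per the deposited text that accompanies each table, reads were placed on the mouse assembly mm10 and counted over the GENCODE M21 annotation. The aligner, its version, the adapter trimming and the counting settings are not given in the sources used here. Each table has 3 value columns. In both libraries the second of these holds nearly all reads at miRNA genes, the third holds few, and the first loses the reads that the strand columns assign to overlapping genes, so the first was read as the count without strand and the others as the counts on 1 strand each. No source used here names the columns. Following a rule fixed before the data were examined, the strand column with the larger total over gene rows was the main one.

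The table opens with 4 rows that name no gene: unmapped reads, reads that match several places, reads outside miRNA genes and reads in more than 1 gene. These rows stayed out of library sizes and tests. Reads that match several places made up 41.9% of the replicate 1 library and 46.4% of the replicate 2 library. Unmapped reads made up 17.1% and 17.2%, and reads outside miRNA genes 5.56% and 5.17%. Because reads with several places are in no gene count, a miRNA whose mature sequence occurs at more than 1 locus is undercounted. Of the 2202 miRNA genes, 1032 share an identical stretch of at least 22 bases with a miRNA gene at another locus, and 69 of these are among the detected genes. Reads of the CAST/EiJ allele that differ from mm10, which was built from C57BL/6J, can also be placed less often, and no allele was analysed here. The counts are per gene, so the 2 arms of a hairpin cannot be told apart.

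All 2202 gene identifiers matched miRNA genes of GENCODE M21, from which symbols, coordinates (mm10, counted from 1) and overlapping genes were taken. CPM, counts per 1000000 counts in the gene rows, were computed here from the gene rows of the main column. A gene was detected when it had a CPM of at least 2 in each library. Levels are mean CPM ± SD over the 2 libraries. Log2 ratios are log2 of (replicate 2 CPM + 1) over (replicate 1 CPM + 1), and folds are ratios of CPM without the added 1, with exact 95% intervals from the counts. Shares of a library carry exact Clopper-Pearson 95% intervals. A count of 0 allows up to 3 counts, which is 0.547 CPM in replicate 1 and 0.703 CPM in replicate 2. Intervals and floors cover counting error only, because PCR copies of a molecule are not independent.

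With 1 group there is no comparison between conditions. The replicates were compared by Pearson and Spearman correlation across detected genes, a chi-square test of homogeneity, and the common dispersion of an intercept-only edgeR fit, given as the biological coefficient of variation (BCV). A two-sided exact binomial test per gene, given the library totals, was run on the 579 genes with at least 10 counts in sum, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares these 2 libraries and not conditions. The 20 lists named below were fixed before the data were examined, from general knowledge of miRNA expression. The miRNA families and the early and late lists of the closing section were drawn up later, when the differences between the libraries were known. A list's level is the median log2(CPM + 1) of its members and its percentile among 10000 random lists of the same size. The mean of the neuron-enriched list was compared with that of 13 lists of other cell types or tissues by two-sided permutation tests, exact or with 100000 resamples, with Benjamini-Hochberg adjustment over the lists. A list's difference between libraries is the median log2 ratio of its detected members and its percentile among 10000 random lists matched on mean expression in 10 bins.

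The 20 lists were neuron-enriched, synaptic and activity-linked, let-7 family, Dlk1-Dio3 imprinted cluster, Mir17-92 and paralogous clusters, oligodendrocyte, microglia and immune, erythroid, endothelial and mural, choroid plexus and ciliated, Hox-embedded caudal, sensory Mir183 cluster, epithelial, striated muscle, liver and gut, pancreas and pituitary, pluripotent and early embryo, spermatogenic X cluster, Sfmbt2 cluster, and entries overlapping rRNA or tRNA. The genes named by rule are the 25 with the highest mean CPM, the 3 detected members of each list with the highest mean CPM, and the 5 with the largest log2 ratio in each direction among tested genes with mean CPM of at least 100 that passed the test. Together these are 66 genes. Any other named gene was chosen after its values were seen.

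The binomial test was tested on simulated counts drawn from the levels and totals of these libraries, with 200 genes changed. It called 48% of 50 genes changed by 1.25-fold, 62% by 1.5-fold, 76% by 2-fold and 80% by 4-fold, and 1.31% of 381 unchanged genes. A simulated BCV of 0.4 was recovered as 0.412. A list of 15 genes shifted by 2 on the log2 scale came out at percentile 100, and an unshifted one at 5.94.

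Alternatives tried were the other columns, other detection floors and pseudocounts, edgeR TMM and DESeq2 size factors in place of library totals, a 1.5-fold minimum, numbered copies summed or left out, and each library left out in turn. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.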

Results

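The data are 2 libraries of short RNA from the hippocampus of 25-day-old female mice, biological replicates 1 and 2 of a single group. They describe which miRNAs with reads that match a single place the young hippocampus holds, and how far 2 samples of it differ. Reads that match several places enter no gene count, so the ranks and shares below undercount miRNAs with copies. The replicate 1 table accounts for 15474606 reads and the replicate 2 table for 13677083. Reads assigned to miRNA genes on the main strand numbered 5481053 in replicate 1, 35.4% of its reads (95% Clopper-Pearson interval 35.40 to 35.44), and 4266963 in replicate 2, 31.2% (31.17 to 31.22). Reads that matched several places were the largest class in both libraries, at 41.9% and 46.4%. At this depth 724 miRNA genes had at least 1 count in replicate 1 and 747 in replicate 2, of 2202 in the table, and 1382 had none in either. A CPM of at least 2 was reached by 482 and 495 genes, and by 433 genes in both libraries, which are the detected genes below.

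**Figure D1:**
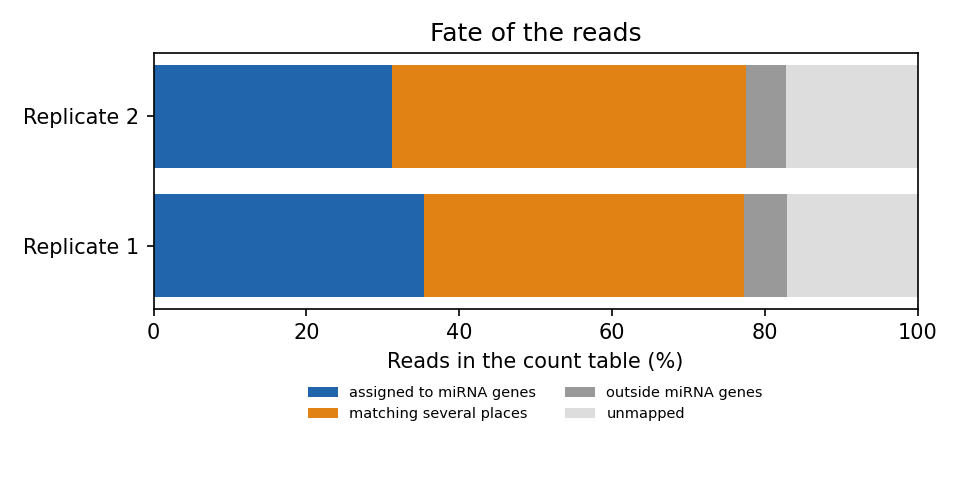
Stacked bars show the percent of reads in each library that were assigned to miRNA genes, matched several places, fell outside miRNA genes or were unmapped. The assigned class holds 35.4% of the replicate 1 reads and 31.2% of the replicate 2 reads, and the class matching several places 41.9% and 46.4%.

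The let-7 family, whose members rise as neurons and other cells differentiate, held the largest share of counts among the lists in both libraries. Its 12 genes were all detected and held 25.0% of the counts in replicate 1 and 32.4% in replicate 2. The 3 miRNA genes with the highest mean CPM belonged to it: Mirlet7b at 91626 ± 11165 CPM (SD, n = 2), Mirlet7g at 70036 ± 17724 and Mirlet7i at 69848 ± 34170. They were also the top 3 in replicate 2, whereas in replicate 1 Mirlet7b was followed by Mir139 (95828 CPM) and Mir127 (71805 CPM). Mirlet7d (22007 ± 10022) and Mirlet7e (21708 ± 826) were also among the 25 most abundant genes. In mm10, Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 from 85707319 to 85707403 in an exon of the noncoding gene Lncppara. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82, and Mirlet7i (ENSMUSG00000065406.3) on chromosome 10 from 122985640 to 122985724 in an exon of the annotated pseudogene D630033A02Rik. Copies such as Mirlet7a-1 and Mirlet7f-1 share their mature sequence with another locus and were at 406 and 118 mean CPM, so their levels are uncertain.

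The imprinted Dlk1-Dio3 cluster on chromosome 12, a large miRNA cluster transcribed from the maternal chromosome, was the second large group. Of its 57 genes, 51 were detected, and they held 17.97% of the counts in replicate 1 and 12.5% in replicate 2. Mir127 (ENSMUSG00000070076.2, chromosome 12 from 109592846 to 109592915) was its most abundant member at 46155 ± 36275 CPM. Mir487b followed at 16268 ± 1366 CPM (109727333 to 109727414), then Mir770 at 14056 ± 2494 CPM, in an exon of the lincRNA Meg3 (109563692 to 109563785). Mir382 (11782 ± 6170) and Mir433 (9799 ± 2445) of the same cluster were also among the 25 most abundant.

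Among neuron-enriched genes, 17 of 21 were detected, and the list held 6.26% of the counts in replicate 1 and 8.43% in replicate 2. The members with the highest mean CPM were Mir149 at 23202 ± 13707 CPM (chromosome 1 from 92850378 to 92850443, in an intron of Gpc1), Mir128-1 at 16713 ± 7221 (chromosome 1 from 128202361 to 128202430, in an intron of R3hdm1) and Mir132, induced by neuronal activity, at 10590 ± 9266 (chromosome 11 from 75173682 to 75173747). Mir137 was at 9705 ± 6200 CPM. The order depends on the library, since Mir132 was highest of the list in replicate 1 (17142 CPM, against 5321 for Mir137) and Mir149 in replicate 2 (32894 CPM), where Mir137 (14089) stood above Mir132 (4038). Mir128-1 and Mir138-1 each share at least 22 bases with a copy at 1 other locus, so their counts are uncertain. All 9 genes of the synaptic and activity-linked list were detected, with 3.75% of the counts in replicate 1 and 2.56% in replicate 2, and the highest mean CPM in Mir132, Mir137 and Mir138-1 (4395 ± 2553 CPM). Mir124a-1, Mir124a-2 and Mir124a-3, whose product is the classic neuronal miRNA, had only 18, 2 and 4 counts in replicate 1 and 20, 13 and 4 in replicate 2. They were chosen for mention after their values were seen. Each shares at least 22 identical bases with 2 other loci, so these counts leave out the reads that match all copies and are no measure of miR-124.

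Other genes among the 25 most abundant were Mir139, in an intron of Pde2a (chromosome 7 from 101475376 to 101475443), at 66951 ± 40838 CPM and Mir744, in an intron of Map2k4 (chromosome 11 from 65734733 to 65734832), at 33228 ± 3320. Mir99a, in an intron of Mir99ahg (chromosome 16 from 77598936 to 77599000), was at 31640 ± 1932 CPM, Mir125a at 18774 ± 1094, Mir99b at 15786 ± 9058 and Mir23b at 15473 ± 8982. Mir652, Mir191, Mir92b and Mir324 were at 13329 ± 6033, 9622 ± 1406, 9104 ± 5849 and 8690 ± 995 CPM. The 10 genes with the highest mean CPM held 48.5% of the counts in replicate 1 and 46.8% in replicate 2, or 47.6% ± 1.21 (SD, n = 2). At least 1000 CPM in both libraries was reached by 87 genes.

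Lists of the other cell types of the brain were present at lower shares. Of the endothelial and mural list, 3 of 5 genes were detected, with 2.20% and 1.29% of the counts in replicates 1 and 2. They were the endothelial Mir126a at 14271 ± 6275 CPM (chromosome 2 from 26591357 to 26591429, in an exon of Egfl7), and the smooth muscle and pericyte genes Mir143 at 3023 ± 107 and Mir145a at 132 ± 26.4. The oligodendrocyte list had 3 of 5 genes detected, with 0.650% and 0.0939% of the counts. Its members Mir219a-2, Mir338 and Mir219a-1 were at 2540 ± 3423, 1148 ± 541 and 33.6 ± 30.0 CPM. The microglia and immune list had 5 of 7 genes detected (0.199% and 0.110%), among them Mir150 at 806 ± 578 CPM, Mir146 at 591 ± 129 and the haematopoietic Mir142 at 70.5 ± 39.1. The choroid plexus and ciliated list had 4 of 6 (0.0982% and 0.230%), among them Mir204 at 759 ± 140, Mir449a at 620 ± 734 and Mir34c at 254 ± 58.0. The erythroid list had 3 of 4 (0.00881% and 0.00659%), with Mir486, Mir451a and Mir144 at 32.5 ± 15.01, 27.7 ± 19.3 and 16.7 ± 11.4 CPM.

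Several lists of tissues that a hippocampal dissection should hold little of were close to the floor. None of the 14 pluripotent and early embryo genes was detected, with 8 counts in all in replicate 1 and 108 in replicate 2, and none of the 19 genes of the spermatogenic X cluster, with 22 and 12 counts. The striated muscle list had 1 of 11 genes detected, Mir206 at 32.4 ± 7.88 CPM. The Hox-embedded caudal list had 2 of 6, Mir10b at 23.4 ± 23.3 CPM and Mir10a at 7.87 ± 0.805. The liver and gut list had 3 of 5, with Mir122, the main hepatocyte miRNA, at 86.5 ± 76.6 CPM, Mir194-2 at 37.3 ± 19.2 and Mir192 at 21.6 ± 8.97. The pancreas and pituitary list had 2 of 5, Mir375 at 159 ± 52.9 and Mir217 at 34.5 ± 44.7. Epithelial genes (6 of 7 detected) and the sensory Mir183 cluster (2 of 3 detected) were low in replicate 1, at 0.0111% and 0.00283% of the counts, and higher in replicate 2, at 0.627% and 0.184%. The Sfmbt2 cluster, a family of near-identical hairpins within introns of Sfmbt2, had 8 of 81 genes detected and 0.179% and 0.198% of the counts, with Mir467d, Mir669c and Mir467e at 931 ± 83.8, 372 ± 32.2 and 287 ± 76.6 CPM. These 3 share at least 22 bases with 14, 37 and 14 miRNA genes at other loci, so their counts are uncertain. Entries overlapping rRNA or tRNA had 4 of 7 genes detected and 0.130% and 0.448% of the counts, with Mir1983, Mir6236 and Mir5099 at 2741 ± 2156, 80.2 ± 38.7 and 57.2 ± 55.6 CPM.

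Set against these 13 lists of other cell types and tissues, the mean log2(CPM + 1) of the neuron-enriched list, 7.59, was higher than that of 4 lists. The difference was 5.85 for the Hox-embedded caudal list (adjusted p = 0.012, permutation test) and 6.74, 7.10 and 7.41 for the striated muscle, pluripotent and spermatogenic lists (adjusted p = 8.67e-05 each, from the smallest p that the permutations can give). It did not pass for the other 9, among them the epithelial list (difference 1.65, adjusted p = 0.432) and the endothelial and mural list (1.13, adjusted p = 0.646, exact permutation test). With only detected members kept, none of 10 comparisons passed, and without members that have a copy number the Hox-embedded caudal list did not pass (adjusted p = 0.0788, exact permutation test). The epithelial and Mir183 differences depend on the library: from replicate 1 alone they were 4.29 (adjusted p = 0.053, permutation test) and 4.99 (adjusted p = 0.145, exact permutation test), and from replicate 2 alone -0.99 (adjusted p = 0.677, permutation test) and -0.86 (adjusted p = 0.762, exact permutation test). Genes of a list are not independent replicates.

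The replicates differed strongly gene by gene while keeping the broad order of abundance. Of the 25 most abundant genes, 16 were in the top 25 of both libraries. Across the 433 detected genes, log2(CPM + 1) correlated with Pearson r = 0.919 and Spearman rho = 0.912. These are correlations across genes, which are not independent replicates. Among the 218 genes with mean CPM of at least 100, the log2 ratio of replicate 2 over replicate 1 had an SD of 1.81 and a median absolute value of 0.96. Of these genes 70 lay within 1.5-fold, 25 were more than 4-fold higher in replicate 2 and 16 more than 4-fold lower. The BCV was 0.666. The chi-square statistic was 1621 per degree of freedom (819 degrees of freedom), so the tables do not hold the same library.

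**Figure D2:**
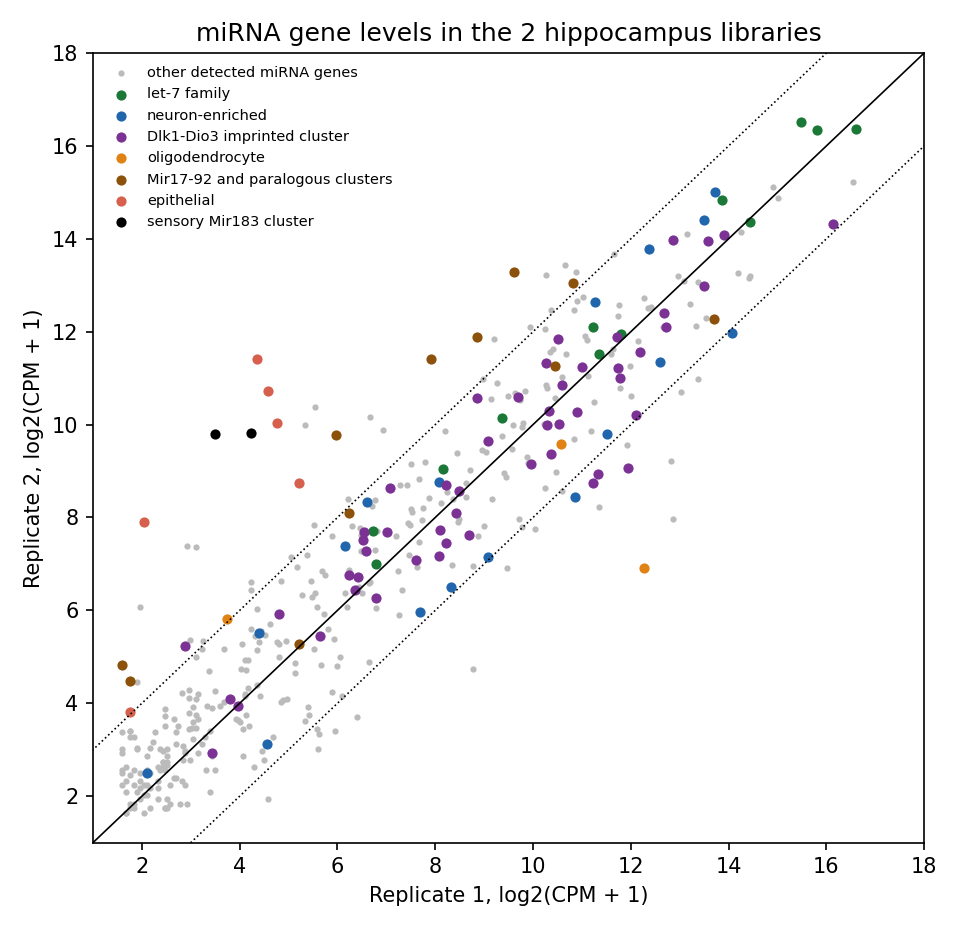
Each dot is a detected miRNA gene, with log2(CPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis. Colours mark members of the named lists, the solid line marks equal values and the dotted lines 4-fold differences. The epithelial genes lie far above the line, with Mir200c at 19.5 and 2706 CPM, and Mir219a-2 lies far below it.

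In the exact binomial test with Benjamini-Hochberg adjustment, 399 of 579 genes differed between the libraries, and 322 of them by at least 1.5-fold. Of the 399, 243 were higher in replicate 2 and 156 lower, so 60.9% were higher. With edgeR TMM scaling 192 of 392 were higher (49.0%), and with DESeq2 size factors 196 of 394 (49.7%), because these scalings move the median log2 ratio of detected genes by -0.29 and -0.27. Both scalings lower the log2 ratios of detected genes, so genes only slightly higher in replicate 2 can turn, while genes lower in it stay lower. All 25 of the most abundant genes passed the test and 14 of them differed by at least 1.5-fold. The test covers counting error only, and with 1 library on each side it says nothing about a condition. With library totals, for all 18 lists with a detected member, the counts adjusted over the list alone equalled those over all genes tested. With TMM the Dlk1-Dio3 list had 30 genes lower over all genes and 31 over the list alone.

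Epithelial miRNAs, of which the miR-200 family represses the mesenchymal factors Zeb1 and Zeb2, were far higher in replicate 2. All 6 detected members were higher, with a median log2 ratio of 5.57, above every one of 10000 matched random lists (percentile 100). Mir200c (ENSMUSG00000065462.3, chromosome 6 from 124718322 to 124718390) went from 19.5 CPM in replicate 1 to 2706 in replicate 2, 139-fold (95% interval 115 to 169). The neighbours Mir200b, Mir200a and Mir429 on chromosome 4 (156053905 to 156055750) were 40.1-fold (34.0 to 47.7), 76.6-fold (47.6 to 132) and 74.4-fold (62.3 to 89.5) higher. The sensory Mir183 cluster on chromosome 6, known from photoreceptors and hair cells, moved with them. Mir182 (30165918 to 30165992) was 87.6-fold (67.3 to 116) and Mir183 (30169668 to 30169737) 50.2-fold (41.1 to 62.0) higher in replicate 2, and the median of the pair lay at percentile 99.96. The third member, Mir96, had 1 count in replicate 1 and 197 in replicate 2, a ratio of 253 with an interval of 44.9 to 10045, and was chosen after its values were seen. Random lists of single genes do not allow for neighbours in a cluster. The epithelial and Mir183 percentiles thus treat such neighbours as independent.

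Genes of the Mir17-92 cluster and its paralogues, which promote proliferation and are high in progenitor cells, were also higher in replicate 2. Of 11 detected members, 9 were higher and 1 lower, with a median log2 ratio of 2.73 (percentile 100), and the list's share was 1.81% in replicate 1 and 3.36% in replicate 2. Neighbours in a cluster limit that percentile in the same way. Mir17 (chromosome 14 from 115043671 to 115043754, in an exon of Mir17hg) was 12.7-fold (12.3 to 13.1) and Mir93 (chromosome 5 from 138165523 to 138165610, in an exon of Mcm7) 4.73-fold (4.63 to 4.84) higher. Mir92b, a list member on chromosome 3, went the other way and was 2.66-fold (2.62 to 2.71) lower in replicate 2. It held 72568 of the list's 99105 counts in replicate 1 and 21199 of 143295 in replicate 2. The list's share in replicate 1 is thus mostly Mir92b, and the change in share understates the rise of the other members as a group.

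The largest difference in the opposite direction among genes with mean CPM of at least 100 was in Mir219a-2, a gene of the oligodendrocyte list. Mir219a-2 (ENSMUSG00000065485.1, chromosome 2 from 29845631 to 29845727), which promotes oligodendrocyte differentiation, went from 4960 CPM in replicate 1 to 119 in replicate 2, 41.6-fold lower (95% interval 38.1 to 45.5). Mir338, with the same known role, was 2.00-fold (1.92 to 2.08) lower, and the weakly expressed Mir219a-1 4.42-fold (3.36 to 5.88) higher. The median log2 ratio of these 3, -1.0, lay inside the central 95% of random lists (percentile 10.4). Mir29a (chromosome 6 from 31062660 to 31062747), of a family that rises as the brain matures, was 29.9-fold (28.2 to 31.9) lower. Mir7080 (chromosome 8 from 123130106 to 123130172, in an exon of Cpne7) was 17.0-fold (14.0 to 20.8), Mir195a (chromosome 11 from 70235042 to 70235135) 12.3-fold (11.8 to 12.8) and Mir346 (chromosome 14 from 34894609 to 34894706, in an intron of Grid1) 8.71-fold (8.22 to 9.23) lower. Mir219a-2 shares at least 22 bases with 1 other locus. Mir219a-2 and Mir338 overlap a miRNA gene on the other strand, and counts without strand hold at most 1 of their reads in either library. Mir219a-1 has the same limits: it shares such a stretch with 2 other loci, overlaps Mir219c and has 3 and 0 counts without strand.

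Synaptic and activity-linked genes had a median log2 ratio of -1.26, below all but 0.675% of matched random lists. That median is the value of Mir138-1, whose counts are uncertain because of its copy. The lower members include the neighbours Mir132 and Mir212 on chromosome 11 and the copies Mir138-1 and Mir138-2. Random lists of single genes do not allow for such pairs, so the percentile does not show a shift of the whole list. Of the 9 members, 5 were lower in replicate 2 and 4 higher, or 3 higher with either other scaling. Mir132 was 4.25-fold (4.18 to 4.31) and Mir138-1 2.39-fold (2.34 to 2.45) lower, whereas Mir137 was 2.65-fold (2.61 to 2.69) higher. The neuron-enriched list, which shares some of these genes, was split with 8 higher, 8 lower and 1 not called, and its median of 0.41 lay at percentile 61.3. Mir149 was 2.43-fold (2.41 to 2.46) and Mir128-1 1.88-fold (1.86 to 1.90) higher in replicate 2.

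**Figure D3:**
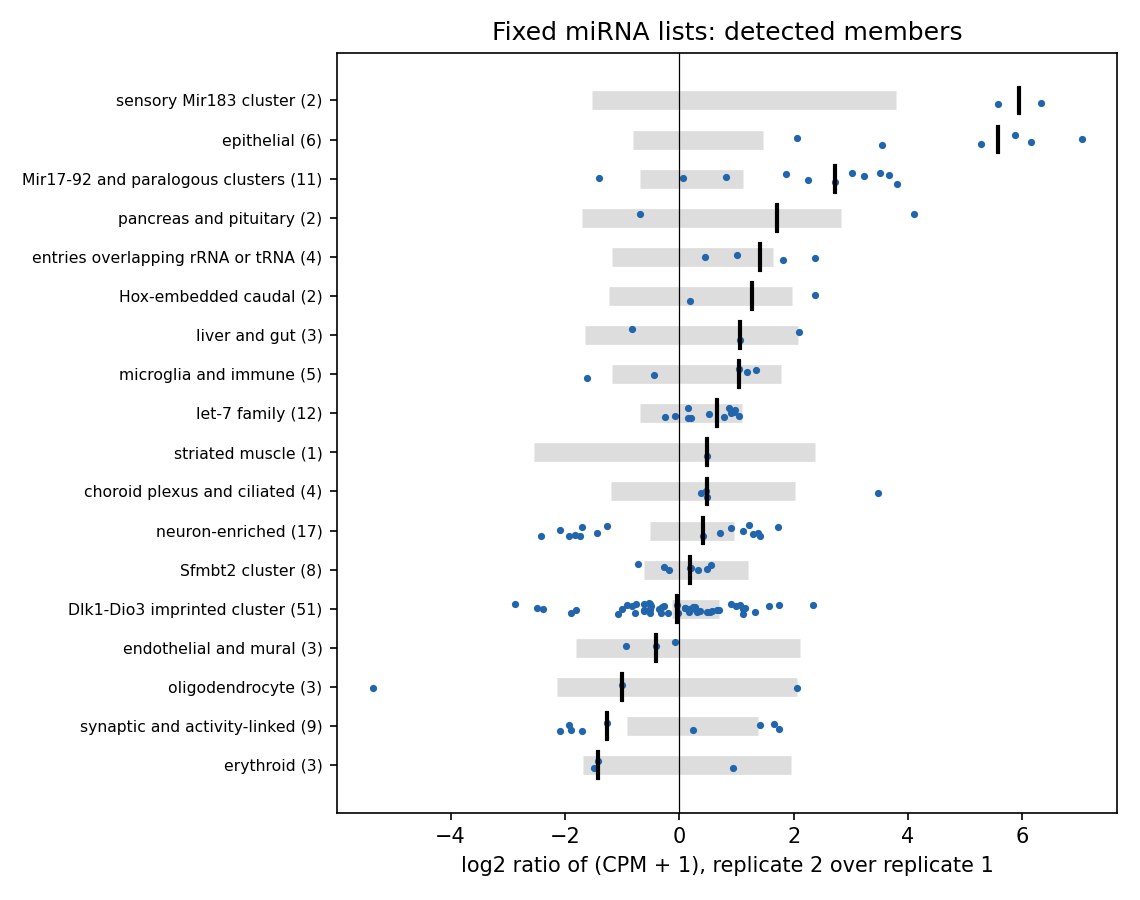
Each dot is the log2 ratio, replicate 2 over replicate 1, of a detected member of a list, and the number in brackets is how many were detected. Black ticks mark the list's median and grey bars the central 95% of medians of 10000 random lists matched on expression. The epithelial, Mir183 and Mir17-92 medians lie above their bars and the synaptic median below its bar, and the other 14 lie inside.

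The let-7 family had 10 members higher and 2 lower in replicate 2 (7 and 4 with either other scaling), with a median log2 ratio of 0.65 inside the random range (percentile 84.1). Mirlet7i was 2.06-fold (2.05 to 2.07) and Mirlet7g 1.44-fold (1.43 to 1.44) higher, and Mirlet7b 1.19-fold (1.18 to 1.19) lower. The Dlk1-Dio3 cluster had 22 members higher, 23 lower and 6 not called, with a median of -0.04 (percentile 6.38), and 16 higher and 30 lower with TMM or 29 lower with DESeq2 size factors. Mir127 was 3.50-fold (3.48 to 3.53) lower, while Mir487b was 1.13-fold (1.12 to 1.14) higher, which turns under both other scalings. Mir744, Mir324 and Mir467d, 1.15-fold, 1.18-fold and 1.14-fold higher in replicate 2, turn in the same way.

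The remaining lists with a detected member lay inside the range of random lists. The pluripotent and spermatogenic lists had none, so no such range was computed for them. All 3 endothelial and mural genes were lower in replicate 2 (median -0.41, percentile 23.6), with Mir126a 1.90-fold (1.88 to 1.92) lower. In the microglia and immune list 3 were higher and 2 lower (median 1.05, percentile 84.4), with Mir150 3.06-fold (2.90 to 3.23) lower and Mir142 2.29-fold (1.95 to 2.70) higher. Of the erythroid genes, Mir451a and Mir144 were lower and Mir486 higher (median -1.42, percentile 5.99). In the choroid plexus and ciliated list 3 of 4 were higher (median 0.48, percentile 57.3), with Mir449a, a gene of multiciliated cells, 11.3-fold (10.3 to 12.3) higher and Mir204 1.30-fold (1.24 to 1.36). Mir10b was 5.75-fold (4.02 to 8.40) higher and Mir10a did not pass (adjusted p = 0.618, exact binomial test), with a median of 1.27 for the pair (percentile 87.7). Mir122 and Mir194-2 were higher and Mir192 lower (median 1.07, percentile 77.8), and Mir217 was 22.6-fold (13.7 to 40.2) higher with Mir375 1.61-fold (1.45 to 1.80) lower (median 1.71, percentile 89.9). With a detection floor of 10 CPM the pancreas and pituitary median turned to -0.69, since Mir217 (2.92 CPM in replicate 1) drops out. At that floor the erythroid median was -0.27 and the microglia and immune median 0.30. Mir206 had a log2 ratio of 0.49 (percentile 44.8) and was not called under the other scalings. The Sfmbt2 cluster, in which the 3 named genes have uncertain counts, had 3 higher and 2 lower (median 0.19, percentile 39.9), or 1 and 4 with either other scaling. Entries overlapping rRNA or tRNA had 3 higher and 1 not called (median 1.41, percentile 94.7), with Mir1983 3.51-fold (3.41 to 3.61) higher.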

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

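The tests of counting error, of non-neural RNA, of epithelial RNA, of clusters without 4 lists (epithelial, Mir183, Mir17-92 and oligodendrocyte) and of early and late genes without shared stretches were chosen after the results were seen. The remaining tests were written before their values were computed. Relatives and cluster neighbours of several early and late genes had been seen by then, and 1 early gene, Mir363, was itself in the Mir17-92 list. Genes of 1 cluster are not independent. The design has 1 group, so no biological explanation was tested through a group. Tests for a sample far from the others and for a difference between groups do not apply to 1 group of 2.

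Counts that the report does not analyse lie far above what a count of 0 allows. The opposite-strand column held 419060 reads at miRNA genes in replicate 1 and 253077 in replicate 2. Of these, 418831 and 252905 lie at genes that overlap a miRNA gene on the other strand, for example 122182 and 90136 at Gm25927, which lies across Mirlet7e and matches its main-strand count. The same numbers were ambiguous without strand, so the main column already holds these reads at the overlapping gene. Reads outside miRNA genes numbered 860873 and 707581. Reads that matched several places numbered 6481877 and 6343330.

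Textbook brain miRNAs such as miR-124 and miR-9 stood at low counts while more reads matched several places than entered any gene count. Reads that match several loci and drop out of the gene counts would lower genes with copies, and in the neuron-enriched and let-7 lists the 21 genes that share at least 22 bases with another miRNA locus had a lower mean log2(CPM + 1) than the 12 others (difference -5.64, permutation p = 0.00046). Their median CPM was 156 against 16149. This is consistent with lost reads as a source of the low counts. Genes with copies may also be transcribed less per locus, which this test leaves open.

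The log2 ratios between the libraries spread widely, with an SD of 1.81 over genes with mean CPM of at least 100. Simulated counting error alone gave an SD of at most 0.0486 in 100 pairs, but separate tissue samples differ by more than counting in any case, so this value decides nothing about the cause. A bias that depends on the sequence of each miRNA would leave unlike neighbours in a genomic cluster no more alike than shuffled genes, but their mean absolute difference was 1.06 in 26 clusters outside Dlk1-Dio3 (2.5th percentile of shuffles 1.28, permutation p = 0.0012), 0.99 without those 4 lists (1.11, p = 0.0044) and 1.18 within Dlk1-Dio3 (1.41, p = 0.0009). The clusters outside Dlk1-Dio3 without those 4 lists argue against such a bias as the whole cause. That value is a mean over clusters, and some neighbours, picked after their values were seen, differed widely. Mir195a had a log2 ratio of -3.62 and Mir497 beside it 0.42, and Mir99b had -1.24 and Mirlet7e beside it -0.08. Unlike here means that no stretch of 10 bases is shared, so related hairpins may still share a bias. The Dlk1-Dio3 shuffles drew on all detected genes, with those 4 lists included. At a mean CPM of at least 100, other genes spread more than Dlk1-Dio3 genes (SD 1.93 against 1.09). The Dlk1-Dio3 value may reflect only that wider pool, so it decides nothing here. Detected Dlk1-Dio3 genes still spread with an SD of 1.06. A difference between the 2 tissue samples and a bias for part of the genes both stay open.

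In replicate 2, miR-200, Mir183 and Mir17-92 genes were higher and Mir219a-2, Mir29a and Mir195a lower. Non-neural RNA mixed in would dilute neuron-enriched genes by as much as the lowered genes. The neuron-enriched median log2 ratio was 0.41 (95% bootstrap interval over genes -1.73 to 1.22), against -3.62 for the least lowered of the 3. These 3 were picked from the largest falls, so a list median above them was likely in any case. The values show only that neuron-enriched genes did not fall as far as these 3, and a smaller dilution stays open. For the raised part, all 6 detected epithelial genes were higher, which epithelial RNA and a different tissue or stage both allow, so these cannot be told apart by that count. If the library came from younger neural tissue than labelled, genes of the embryonic brain should stand above genes that rise after birth. The 8 early genes had a median of 1.99 against -0.42 for 14 late ones (difference 2.41, exact permutation p = 0.013). Of the early genes, Mir363 (log2 ratio 3.23) also belongs to the Mir17-92 list, whose rise was to be explained. Of the late genes, Mir29b-1 and Mir29b-2 are relatives of the lowered Mir29a, and Mir497 is a neighbour of the lowered Mir195a. The lists are thus not fully separate from the pattern. Moreover, 6 of the late genes share a stretch with another locus and have uncertain counts. Without these 6 the difference was 1.48 (late median 0.51, exact permutation p = 0.142). The negative late median thus rests on those copies, and younger tissue is neither shown nor excluded. Single values seen before went both ways. Of the 14 late genes, 5 had log2 ratios above 0 (Mir101a 2.30, Mir30b 1.31, Mir101b 0.95, Mir30e 0.59 and Mir497 0.42). Of the 8 early genes, 2 lay below 0 (Mir301 -0.76 and Mir351 -0.11). The let-7 share was higher (25.0% and 32.4%) and Mir92b lower (-1.41). On the other side, the miR-29 family was lower for 4 of 4 genes (0.828% and 0.0398% of the counts), and Mir302d had 0 and 42 counts. Of the 4 miR-29 genes, however, 3 share a stretch with another locus and have uncertain counts. The other, Mir29a (7438 CPM in replicate 1 and 248 in replicate 2), is part of the pattern to be explained and holds most of that share. The sign of small ratios depends on scaling, since TMM and DESeq2 size factors move the median of detected genes by -0.29 and -0.27. With either, let-7 genes were 7 higher and 4 lower. A mislabelled sample, a different piece of tissue or a mixture stay open.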

How the results depend on the processing

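The added alternatives, chosen after seeing the data, left out genes sharing 22 bases, left out 4 lists (epithelial, Mir183, Mir17-92 and oligodendrocyte), left out each library for the share of reads assigned, and used a pseudocount of 10 for list differences. The detected genes numbered 300 to 555 under other floors and the column without strand, and 482 to 495 with 1 library left out, against 433. The genes differing numbered 322 to 411 against 399, of which 362 were shared with TMM and 365 with DESeq2 size factors. The lists outside the random range numbered 4 under each scaling and a pseudocount of 10, and 5 at a CPM of at least 10, where entries overlapping rRNA or tRNA joined. The share of reads assigned, 33.3% as the mean of both libraries, was 31.2% to 35.4% with 1 library left out and 2.28% in the opposite strand column, by construction. The share of the 10 most abundant genes moved from 47.6% to 50.8% without strand and 44.4% without the most abundant gene, and was 46.8% to 48.5% with 1 library left out. Pearson r moved from 0.919 to 0.948 with no filter, 0.864 at a CPM of at least 10 and 0.942 without the 4 lists, while the BCV stayed between 0.586 and 0.758. With only detected members, 0 of 10 lists passed as lower than the neuron-enriched list, against 4 of 13. Of those 4, the striated muscle, pluripotent and spermatogenic lists had 1, 0 and 0 detected members and were not compared. The Hox-embedded caudal list kept 2 members and a difference of 5.45 (adjusted p = 0.215, exact permutation test). Without members that have a copy number 3 of 13 passed, the Hox-embedded caudal list (adjusted p = 0.0788, exact permutation test) no longer among them. Log2 ratios turned under TMM and DESeq2 size factors for Mir744 (-0.095 and -0.070), Mir487b (-0.13 and -0.10), Mir324 (-0.065 and -0.040) and Mir467d (-0.12 and -0.090), all smaller than the shift of the median. Without strand, 10 of 106 named log2 ratios lost their call, including Mirlet7e, Mir126a, Mir191 and Mir219a-2, because reads at overlapping genes then count for neither. Agreement, differing genes and list differences need both libraries, so none has a value with 1 left out. No paired analysis was possible because there is 1 group. Depth limits genes near the floors of 0.547 and 0.703 CPM.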

Other observations

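Further families were grouped after their values were seen, and no family was tested as a unit. The miR-29 family, known to restrain DNA methylation and matrix genes in maturing cells, was lower in replicate 2 for 4 of 4 detected genes, with 0.828% of the counts in replicate 1 and 0.0398% in replicate 2. Mir29c was 5.89-fold (5.37 to 6.48) lower, Mir29b-2 6.93-fold (5.18 to 9.45) and Mir29b-1 3.28-fold (2.55 to 4.27), but these 3 share at least 22 bases with another locus and their counts are uncertain. Genes of miR-23, miR-27 and miR-24, which are separate families grouped here, had 0 higher and 5 lower of 6 detected, or 6 lower with either other scaling. Of the 6, 2 have such a stretch, and the group held 3.03% and 1.44% of the counts. The miR-181 family, in which 4 of 6 genes share such a stretch, had 5 higher and 1 lower, with 0.642% and 2.46%, Mir181d being 5.29-fold (5.18 to 5.40) higher. The miR-130 and miR-301 family had 3 higher and 1 lower, with 0.224% and 1.28%, Mir130a being 6.84-fold (6.69 to 7.001) higher. The counts of miR-29, miR-181 and miR-130 and miR-301 were the same with TMM and DESeq2 size factors.

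The miR-30 family had 4 higher and 2 lower. The miR-15 and miR-16 family had 5 higher and 1 lower (4 and 3 with TMM, 4 and 2 with DESeq2 size factors). The miR-125 family was split 2 and 2, and the miR-34 and miR-449 family 2 and 1. In the miR-99 and miR-100 family 1 was higher and 2 lower, or 3 lower with either other scaling, and in the miR-26 family 1 was higher and 1 lower, or 2 lower. Single genes picked after their values were seen include the imprinted neighbours Mir296 and Mir298 near Gnas on chromosome 2, 7.80-fold (7.604 to 8.01) and 4.08-fold (4.01 to 4.15) higher in replicate 2. Mir135b was 25.8-fold (22.5 to 29.8) higher, and Mir328 5.28-fold (5.16 to 5.40) lower. Mir1247, beside Dio3 at the end of the Dlk1-Dio3 region, had 810 counts in replicate 1 and 7 in replicate 2, 90.1-fold (43.5 to 225) lower. Mir302d, of a cluster active in pluripotent cells, had 0 and 42 counts, at least 17.98-fold higher against a floor of 3 counts, and its neighbours Mir302a and Mir302c had 0 and 18, and 0 and 9.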
